A study of Mus musculus with 15 samples.

How the data were processed

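Microglia were sorted from mouse brain, and libraries were made with Smart-seq2, a method that amplifies full-length cDNA from few cells, from 1000 cells each. They were sequenced as paired reads of 25 bases per the labels. Mice of the treated groups received 200 ul of a B. fragilis suspension by mouth (OD 0.7, read at 600 nm). Dosing began when they were 2.5 months old and lasted 10 weeks; these details are stated for B. fragilis only. The 15 libraries were grouped by genotype and treatment as labelled. The labels give plate wells and no replicate numbers, so replicates are numbered here by their order in the labels. No paired analysis was possible because the labels link no library of one group to a library of another.

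The authors deposited 1 table of values for the 15 libraries and 4 tables of comparisons. The deposited table of values holds normalized counts, a signal that the authors scaled between libraries; their notes name DESeq2, with the version not given, and the aligner and genome build are not given in the sources used here. The table lists 2794 genes, of which 37 have no value in any library, and the lowest gene mean is 99.6, so weakly expressed genes are absent. Libraries were checked for whole reads: at the best step tried, the share of low values within 0.1 of a whole number was 0.261, so reads were not recovered, depth is unknown and no count model was fitted. The totals of 1029486 to 1135005 are sums of normalized values and not depth. Group means of these totals were 1058600 ± 23681 (SD, n = 4) for wild type given PBS, 1055012 ± 15490 (n = 4) for wild type given B. fragilis, 1111131 ± 20675 (n = 3) for APPPS1 given PBS and 1040258 ± 7321 (n = 4) for APPPS1 given B. fragilis. Libraries of 1 group correlated with r of 0.858 to 0.949 across genes. In the comparison tables the authors give for each gene a mean signal, a log2 fold change on the log2 scale with its standard error, a Wald score, and a p-value with its adjusted p-value; these were compared with the values computed here and not refitted.

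Values were analysed as log2(normalized count + 1). Genes with a normalized count of at least 10 in at least 3 libraries were kept, which removed 0 of 2757 genes. Limma 3.58.1 in R 4.3.3 fitted the 4 group means with a mean-variance trend (lmFit, contrasts.fit and eBayes with trend), two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05. The comparisons were B. fragilis against PBS in each genotype, APPPS1 against wild type under each treatment, the difference of the B. fragilis effect between genotypes, and the mean effect of each factor. Gene lists were tested with camera, limma's competitive test of a list against all other genes, with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison; camera with an estimated correlation and fry, limma's test of whether a list's genes move one way, were run beside it. Of the lists fixed before the data were examined, 15 had at least 3 measured members: homeostatic, plaque-associated, phagocytosis, lysosome, proteasome, type I interferon response, antigen presentation, inflammatory, complement, immediate early and dissociation, oxidative phosphorylation, cytosolic ribosomal protein, glycolysis, cholesterol and lipid handling, and TGF-beta signalling genes. The mitochondrial genome list had 0 measured genes and the cell cycle list had 1, Pcna, so neither was tested. Lists can share members, since Cd63, Cd68, Ctsb, Ctsd, Ctsl and Ctsz are in both the plaque-associated and the lysosomal list. Among others, the plaque-associated list also shares Apoe and Lpl with the lipid-handling list. It shares B2m with the antigen presentation list and Ccl3 and Ccl4 with the inflammatory list. Counts of list members that rose or fell are of genes past the limma threshold over all genes, unless said otherwise. Markers of 12 other cell types were also listed; 0 of these types had 3 measured markers, and those measured were Slc1a3 (astrocyte), Cnp (oligodendrocyte), Bsg (endothelial), Stab1 (border-associated macrophage), Csf3r (neutrophil), Ighm (B cell) and Ttr (choroid plexus), with none for neurons, mural cells, monocytes, T or NK cells and erythroid cells.

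Named genes were chosen by a rule fixed before the data were examined. For each pairwise comparison the rule takes the 10 genes with the largest rise and the 10 with the largest fall in log2 fold change among those with an adjusted p under 0.05, a mean of at least 50 and no overlap between the groups' libraries, without predicted genes and pseudogenes, filled to 5 per direction by smallest p where fewer pass. It adds 2 to 4 members of each described list with the smallest p, and Apoe, Trem2, Tyrobp, Cst7, Clec7a, Itgax, Lpl, Axl, P2ry12, Tmem119, Cx3cr1 and Cd68 in every comparison, and gives App, Prnp and Thy1 as a check of the genotype labels. Some genes that the rule picks are not reported here. For the difference between genotypes and the mean effects it takes the 5 genes with the smallest p in each direction. Correlations of fold changes across genes were compared with 1000 relabellings of the residuals, which keep the libraries that 2 comparisons share.

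Alternatives fixed before the data were examined were other pseudocounts (0.5 and 10), no filter, a mean of at least 50, rescaling by 1 upper quartile per library, quantile normalization, array quality weights, a fit of the compared groups alone, estimated correlation and fry for lists, and each library left out in turn. Removing each library's trend with GC content and exonic length, or with expression level as well, was added after seeing the data. Exonic length and GC content came from a GENCODE mouse annotation that need not be the authors' and covered 2755 genes (99.9%). Shared sequences were counted as 25-base stretches of a gene's transcripts that also occur in transcripts of other genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

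The procedure was tested on simulated data with the same groups and 200 changed genes, spread over fold changes of 1.5, 2 and 4. At a fold change of 2 it recovered 88.1% of changed genes for B. fragilis in wild type, 83.6% for B. fragilis in APPPS1, 70.1% and 89.6% for the genotype under PBS and under B. fragilis, and 49.3% for the difference between genotypes; at 1.5 the shares were 41.8%, 46.3%, 47.8%, 40.3% and 22.4%. False calls made up 0.909% to 6.45% of calls. Simulated genes varied independently of each other, so these shares need not hold where genes vary together. A simulated trend with length, without any other change, gave 611 calls, and 0 after the trend was removed. The removal models the same length term, so this outcome was fixed in advance and does not show what happens to real changes.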

Results

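Gene expression was measured in microglia, the resident macrophages of the brain, from wild-type mice and from APPPS1 mice, which carry human transgenes and develop amyloid plaques. Mice received the gut bacterium Bacteroides fragilis by mouth or phosphate-buffered saline (PBS). There were 15 libraries, each from 1000 sorted cells, with n = 4 for wild type given PBS, n = 4 for wild type given B. fragilis, n = 3 for APPPS1 given PBS and n = 4 for APPPS1 given B. fragilis. The comparisons ask what the genotype does, what the treatment does in each genotype, and whether the treatment effect differs between genotypes. Values are normalized counts, for 2757 genes whose lowest mean over the libraries was 99.6, so weakly expressed genes are not represented. The normalized totals ran from 1029486 to 1135005 per library. Read depth is unknown, because no step tried turned the values back into whole reads. The labels do not say whether each library came from a separate animal, so the p-values measure the spread between these samples. Each of the 4 groups occupied its own stretch of wells on the plate, so plate position runs with treatment and, within each treatment, with genotype.

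The mouse gene App was examined first, although the transgenes are human sequences that mouse gene values need not show. App had 126 ± 41.0 normalized counts (mean ± SD, n = 4) in wild type given PBS and 119.8 ± 15.6 (n = 3) in APPPS1 given PBS. With B. fragilis, App had 128 ± 9.40 in wild type and 137 ± 23.1 in APPPS1 (n = 4 each). It did not pass in any of the 4 pairwise comparisons by limma, with a smallest adjusted p of 0.561. Prnp and Thy1 were not analysed here. Reads were 25 bases long, and for some genes named here many 25-base sequences also occur in transcripts of other genes, so their values are uncertain: 96.9% for Rpl36, 71.2% for Hspa1a, 65.6% for Srcap, 63.2% for Zfp36l1, 55.2% for Pgk1, 52.1% for Rac1, 51.3% for Rpl32, 51.1% for Rps2, 46.7% for Rps4x, 46.6% for H2-Q7, 45.9% for Rplp0, 40.6% for Gmpr2 and 40.5% for Lyz2. In a principal component analysis, component 1 held 27% of the variance. The 4 APPPS1 libraries given B. fragilis scored 9.79 to 17.3 on it, replicate 2 of wild type given B. fragilis scored 14.6, and every other library scored -0.977 or less.

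APPPS1 microglia given PBS had higher expression of plaque-associated genes than wild-type microglia given PBS. Cst7, which encodes the cysteine protease inhibitor cystatin F, rose from 16.97 ± 6.95 (SD, n = 4) to 1127 ± 507 (SD, n = 3), a log2 fold change of 5.95 with a limma adjusted p of 1.79e-08. Apoe, the lipid carrier apolipoprotein E, rose from 574 ± 164 to 4565 ± 2520 (log2 2.90). The galectin-binding glycoprotein gene Lgals3bp rose from 170.1 ± 56.7 to 733 ± 264 (log2 2.10), and Ifi27l2a, an interferon-induced gene, from 37.6 ± 7.39 to 273 ± 103 (log2 2.78). Other large rises were those of H2-Q7 (1.74), Ank, a membrane transporter gene (1.71), the heparan sulfate proteoglycan gene Sdc3 (1.41), Ramp1 (1.40), the lysozyme gene Lyz2 (1.32) and Cd52 (1.31). Among genes whose libraries did not overlap between the groups, the largest falls in log2 fold change were those of the chromatin remodeller gene Ep400 (-1.42), the transcription repressor gene Zbtb7a (-1.34), Birc6 (-1.29), the flippase subunit gene Tmem30a (-1.12), Rubcnl (-1.08), Asap1 (-1.06), Letm1 (-1.05), Tmem259 (-1.05), Clptm1 (-0.98) and Tmx4 (-0.93). Limma called 175 genes in this comparison, 131 higher and 44 lower in APPPS1.

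Of 18 measured plaque-associated genes, 17 rose, with a median log2 fold change of 0.73 and a camera adjusted p of 4.09e-26. Here and below, list members counted as rising or falling are those past the limma threshold. By sign alone, all 18 plaque-associated genes were higher. Within this list Tyrobp, the signalling adaptor of TREM2, rose by 0.78 on the log2 scale, Trem2 itself by 0.51, the cathepsin gene Ctsz by 0.64 and the lysosomal glycoprotein gene Cd68 by 0.55. The lipoprotein lipase gene Lpl was the member that did not pass (log2 0.95, limma adjusted p 0.0536). Axl and Clec7a have no values per library, and in the authors' deposited table their log2 fold changes were 1.90 (adjusted p 1.31e-10) and 2.03 (adjusted p 6.47e-16). Itgax was not analysed here. Lysosomal genes rose in 14 of 39 cases (median 0.27, camera adjusted p 2.12e-08), among them Npc2, a cholesterol carrier of the lysosome (0.64), Ctsd (0.59) and Hexa (0.54). Of the 14, Ctsb, Ctsd, Ctsl, Ctsz, Cd63 and Cd68 are also in the plaque-associated list. Of 8 type I interferon response genes 4 rose, namely Lgals3bp, Ifi27l2a, Bst2 (0.99) and Ly6e (0.65), with a median of 0.81 and a camera adjusted p of 4.32e-07. Cytosolic ribosomal protein genes rose in 54 of 76 cases (median 0.54, camera adjusted p 8.24e-44; 30 cases and 0.365 with the within-library trend with GC content and exonic length removed; before removal, fold changes across genes followed exonic length with a Spearman's rho of -0.321), for example Rpl41 from 741 ± 26.5 to 1312 ± 178, Rps19 (0.77) and Rpl32 (0.79). With an estimated correlation between genes, camera gave these 4 lists adjusted p = 0.00366, 0.0456, 0.0456 and 0.0254, in the order given.

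Further lists passed camera with the preset correlation and not with an estimated one. Glycolysis genes rose in 5 of 14 cases (median 0.44, camera adjusted p 0.000143, and adjusted p = 0.0849 with an estimated correlation), including Tpi1 (1.01), Pgk1 (0.78), Gapdh (0.55) and Aldoa (0.42). Nuclear genes of oxidative phosphorylation rose in 3 of 46 cases, Cox6b1 (0.63), Uqcrh (0.65) and Ndufa2 (0.64), with a camera adjusted p of 2.43e-05 and an adjusted p = 0.0849 with an estimated correlation. By sign alone, 40 of the 46 were higher. After removal of the within-library trend with GC content and exonic length, this list (median 0.27, then 0.08) had a camera adjusted p of 0.119, and none of the 3 genes kept its call. Antigen presentation genes rose in 4 of 16 cases, H2-Q7, H2-D1 (1.05), B2m (0.73) and H2-K1 (0.78), with a camera adjusted p of 0.000146 and an adjusted p = 0.0849 with an estimated correlation. Inflammatory genes rose in 4 of 17 cases, Cxcl16 (1.06), Ccl3 (0.67), Ccl4 (0.62) and Cd83 (0.54), with a camera adjusted p of 0.00132 and an adjusted p = 0.105 with an estimated correlation. After the same removal this list (median 0.23, then 0.04) had a camera adjusted p of 0.0833, and of the 4 genes Cxcl16 kept its call. Lipid-handling genes rose in 2 of 9 cases, Apoe and Npc2 (camera adjusted p 0.0211, and adjusted p = 0.0804 with an estimated correlation), with a median of 0.02 and a mean of 0.47. Apoe, B2m, Ccl3 and Ccl4 are also in the plaque-associated list, and Npc2 is also in the lysosomal list. Homeostatic microglia genes fell in 3 of 20 cases, among them the receptor genes P2ry13 (-0.58) and Gpr34 (-0.60), with a camera adjusted p of 0.000925 and an adjusted p = 0.105 with an estimated correlation. Not passing in that list were P2ry12 (-0.51), Tmem119 (-0.24) and Cx3cr1 (-0.19).

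The other 5 lists did not pass. Members that passed in them were Tyrobp and Trem2 upward and Elmo1 (-0.54) and Rac1 (-0.70) downward among 24 phagocytosis genes (camera adjusted p 0.522), C1qb upward (0.28) and C1qc downward (-1.08) among 8 complement genes (camera adjusted p 0.628), and Ier2 downward (-1.20) among 25 immediate early genes (camera adjusted p 0.246). None of 30 proteasome genes (camera adjusted p 0.0565) or 8 TGF-beta signalling genes (camera adjusted p 0.0514) passed in limma. Replicate 3 of APPPS1 given PBS carries part of the count, since limma called 68 genes without it, 62 of them among the 175. Of the 55 called genes picked by the naming rule, 30 kept their call in each fit that left out 1 library. With the within-library trend with GC content and exonic length removed, limma called 117 genes, 105 of them among the 175. Of the 55 genes, 36 kept their call after this removal, Tyrobp (0.26, limma adjusted p 0.297) and Cd68 (0.25, 0.269) did not, and C1qb turned from 0.28 to -0.03.

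**Figure D1:**
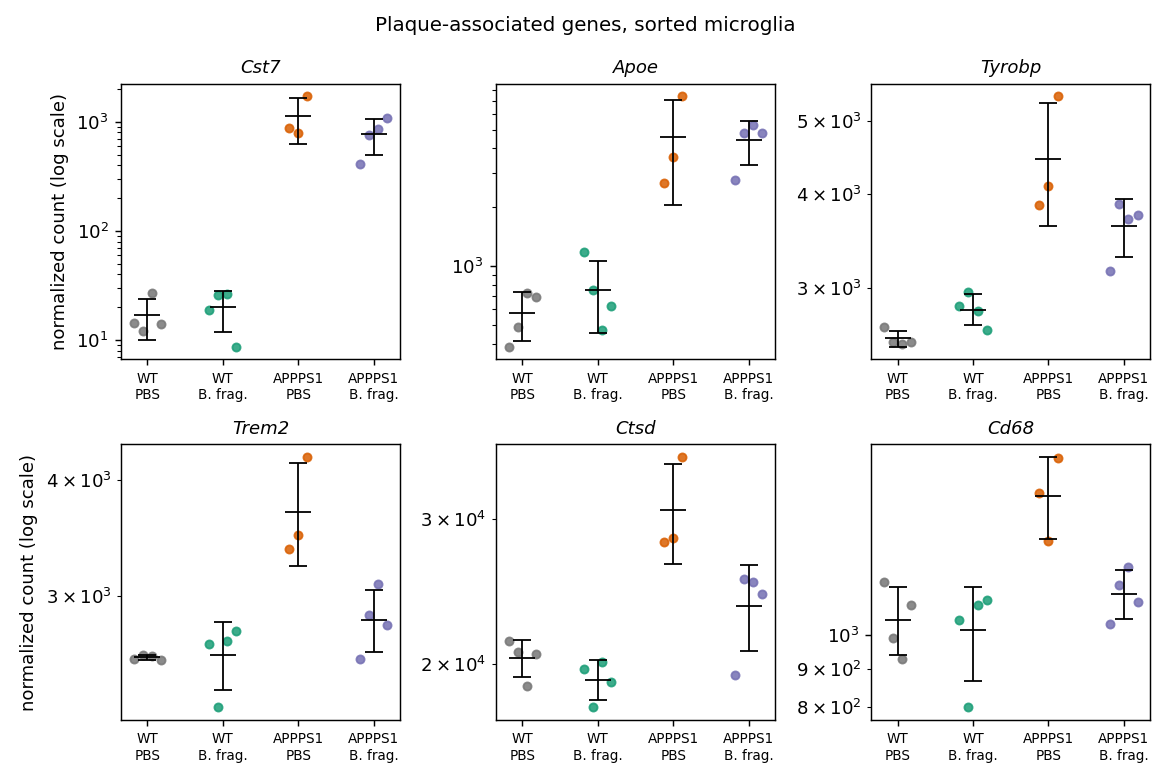
Normalized counts (log scale) of 6 plaque-associated genes in each of the 15 libraries, by genotype and treatment; points are libraries, horizontal bars are means and whiskers are 1 SD. Cst7 and Apoe lie higher in every APPPS1 library than in every wild-type library, under PBS and under B. fragilis alike.

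In wild-type mice, limma called no gene between B. fragilis and PBS. The count was 0 of 2757 tested, with 313 at an unadjusted p under 0.05, a smallest adjusted p of 0.139, and 2 genes, Wdfy3 and Mark2, in the authors' deposited table (adjusted p 0.0181 and 0.0349). Wdfy3, which encodes an autophagy adaptor, had 105 ± 27.6 with PBS and 249 ± 72.4 with B. fragilis (SD, n = 4 each), a log2 fold change of 1.23. The kinase gene Mark2 had 70.4 ± 15.9 and 149 ± 38.4 (1.06). Also with the smallest p and a positive sign were Jade2 (0.90), the RNA-decay factor gene Zfp36l1 (0.48) and the glucocorticoid-induced gene Fkbp5 (0.81). With a negative sign were the microglial receptor genes Gpr34 (2082 ± 314 and 1282 ± 232, log2 -0.70), P2ry12 (4561 ± 407 and 2855 ± 639, log2 -0.70) and P2ry13 (-0.51), and also Scoc (-0.73) and Nras (-0.78). None of these passed, nor did Apoe (0.36), Cst7 (0.19), Trem2 (0.01), Tyrobp (0.13), Lpl (-0.10), Cd68 (-0.05), Tmem119 (-0.10) or Cx3cr1 (-0.09).

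As groups, immediate early and dissociation genes rose in wild type, with a median of 0.27 over 25 genes and a camera adjusted p of 1.23e-06, and homeostatic microglia genes fell, with a median of -0.09 over 20 genes and a camera adjusted p of 0.00602. With an estimated correlation both had adjusted p = 0.584, and neither passed the fry test. No member passed over all genes; adjusted over the list alone, 6 immediate early genes rose and 4 homeostatic genes fell in limma. The immediate early genes with the smallest p were Egr1 (0.38), Atf3 (0.51), Ier5 (0.52) and Rhob (0.49), and the homeostatic ones included Gpr34, P2ry13 and P2ry12. Of the 13 lists that did not pass, lysosomal genes came closest (median -0.06, camera adjusted p 0.096). With the within-library trend with GC content and exonic length removed, the lysosomal list passed downward (-0.06, camera adjusted p 0.0252) and the ribosomal list upward (0.06, 0.0157). The homeostatic list had a camera adjusted p of 0.0558 without replicate 2 of wild type given B. fragilis, and limma called 8 genes without replicate 3 of that group.

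In APPPS1 mice, B. fragilis was accompanied by lower expression of lysosomal genes and higher expression of, among others, Lars2, Zbtb7a and Srrm2, although the lysosomal list passed camera with the preset correlation (adjusted p 3.07e-07) and not with an estimated one (adjusted p = 0.25). Ctsl, encoding the protease cathepsin L, fell from 1994 ± 100 (SD, n = 3) to 957 ± 63.0 (SD, n = 4), a log2 fold change of -1.06 with a limma adjusted p of 0.00234. Ctsb, encoding cathepsin B, fell from 6459 ± 843 to 4138 ± 359 (-0.64). Lars2, the mitochondrial leucyl-tRNA synthetase gene, rose from 3613 ± 642 to 10570 ± 1550 (log2 1.55), Zbtb7a from 45.8 ± 19.7 to 176 ± 31.9 (1.98) and the splicing factor gene Srrm2 from 343 ± 118 to 949 ± 106 (1.51). Of the short sequences of Lars2, 1.9% also occur in transcripts of other genes. That search covered annotated transcripts only. Whether reads from other sequences were counted as Lars2, here and below, was not tested. Other large rises were those of Iqcn (1.66), Msln (1.64), Tmem259 (1.63), the RNA helicase gene Ythdc2 (1.49), the transcription factor gene Klf13 (1.48), Myo7a (1.47) and Rbm4b (1.47). The other large falls were those of the heat shock protein gene Hspa1a (-1.43), Cdk4 (-1.22), Cln8 (-1.21), Skp1 (-1.07), the signal peptidase gene Sec11a (-1.04), Pias1 (-1.02), Imp4 (-1.01), the proton pump accessory gene Atp6ap2 (-0.99) and Gosr2 (-0.99). Limma called 428 genes, 206 higher and 222 lower with B. fragilis.

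Lysosomal genes fell in 18 of 39 cases and rose in 0, with a median of -0.39 and a camera adjusted p of 3.07e-07 (adjusted p = 0.25 with an estimated correlation, and fry adjusted p 0.000467). By sign alone, 34 were lower and 5 higher. Adjusted over the list alone, 24 fell and 3 rose in limma. Besides Ctsl and Ctsb, the falls included Ctsa (-0.57). Plaque-associated genes fell in 6 of 18 cases (median -0.29, camera adjusted p 0.00179, and -0.11 with adjusted p 0.0767 under quantile normalization), including the tetraspanin gene Cd9, from 2040 ± 83.0 to 1242 ± 128 (-0.72), Trem2, from 3695 ± 468 to 2827 ± 214 (-0.38), Cd68 (-0.43), Ctsl and Ctsb. Of the 6, Cd68, Ctsd, Ctsb and Ctsl also belong to the lysosomal list, so the falls of these lists are not separate results. Apoe (0.05, limma adjusted p 0.936), Cst7 (-0.53, 0.342), Tyrobp (-0.29, 0.0638) and Lpl (-0.04, 0.936) did not pass. In the authors' deposited table, Clec7a had a log2 fold change of -0.79 (adjusted p 0.0128) and Axl one of -0.22 (adjusted p 0.546). Homeostatic genes fell in 7 of 20 cases and rose in 2 (camera adjusted p 0.0482, and 0.912 under quantile normalization), with P2ry12 (-0.59) and Olfml3 (-0.33) among the falls, and Tmem119 (-0.08) and Cx3cr1 (-0.11) not passing. TGF-beta signalling genes rose in 4 of 8 cases, the receptor genes Tgfbr1 (0.41) and Tgfbr2 (0.47) and the pathway inhibitor genes Ski (0.46) and Smad7 (0.69), with a median of 0.44 and a camera adjusted p of 0.0184. With an estimated correlation, camera gave adjusted p = 0.405 for the plaque-associated, 0.459 for the homeostatic and 0.383 for the TGF-beta list. Fry, which does not set a list against other genes, gave adjusted p of 0.0138, 0.0278 and 0.0137 in the same order. With the preset correlation, the plaque-associated list had a camera adjusted p of 0.0584 without replicate 3 of APPPS1 given PBS, and the homeostatic list had 0.175 and 0.0684 without replicates 1 and 2 of that group and 0.0577 and 0.0701 without replicates 3 and 4 of APPPS1 given B. fragilis.

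Ribosomal protein genes fell in 12 of 76 cases and rose in 1 (median -0.24, camera adjusted p 3.07e-07, and adjusted p = 0.459 with an estimated correlation), with falls of Rplp0 (-0.52) and Rps4x (-0.47) and a rise of Rps2 (1.10). By sign alone, 72 of these 76 genes were lower, as were 28 of 30 proteasome and 38 of 46 oxidative phosphorylation genes. Proteasome genes fell in 3 of 30 cases, Psma1 (-0.76), Psmb2 (-0.69) and Psmc5 (-0.55), with a camera adjusted p of 0.00365 and an adjusted p = 0.383 with an estimated correlation. Oxidative phosphorylation genes fell in 2 of 46 cases, Atp5a1 (-0.57) and Uqcrc2 (-0.72), with a camera adjusted p of 0.0213 and an adjusted p = 0.459 with an estimated correlation; the former was 0.133 without replicate 3 of APPPS1 given PBS and 0.0528 without replicate 1 of APPPS1 given B. fragilis. The other 8 lists did not pass camera, but single members did in limma. Immediate early genes rose in 6 of 25 cases, among them the GTPase gene Rhob (0.95), Ier5 (0.83) and Ier2 (1.33), while Hspa1a fell (median 0.09, camera adjusted p 0.132, and 0.00395 with quantile normalization). Among 8 complement genes C1qc rose (1.19) while C1qa (-0.35) and C1qb (-0.25) fell (camera adjusted p 0.606). Of 24 phagocytosis genes 2 rose, Rac1 (0.76) and Stab1 (0.79), and 5 fell, among them Trem2 and Fcer1g (-0.39; camera adjusted p 0.16). Of 17 inflammatory genes, Nfkbiz (0.67) and Nfkb2 (0.61) rose and Socs3 (-0.52) and Cd83 (-0.47) fell (camera adjusted p 0.769). Of 14 glycolysis genes, Pfkfb3 rose (0.78) while Tpi1 (-0.61), Pgam1 (-0.65) and Aldoa (-0.38) fell (camera adjusted p 0.439). Falls of Ly6e (-0.38) among 8 interferon response genes (camera adjusted p 0.949), of Ctss (-0.48) among 16 antigen presentation genes (camera adjusted p 0.569) and of Npc2 (-0.34) among 9 lipid-handling genes (camera adjusted p 0.749) complete the lists.

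Some further measures moved with the same groups. Across genes, the fold change in APPPS1 followed exonic length (Spearman's rho 0.447 over 2755 genes, which are not independent replicates). In the authors' deposited table, 8 predicted genes that hold 62.4% of the summed means, Gm10800 among them, rose by 0.94 to 1.03 on the log2 scale with B. fragilis in APPPS1 (adjusted p 0.000912 to 0.00383). The same 8 genes had 0.09 to 0.17 in wild type (adjusted p 0.822 to 0.934) in the authors' deposited table for that comparison. For APPPS1 against wild type the authors' values were 0.417 to 0.5 given B. fragilis (adjusted p 0.202 to 0.305). Given PBS they were -0.238 to -0.135 (adjusted p 0.649 to 0.848). Genes listed as markers of other cell types moved both ways in APPPS1. The astrocyte gene Slc1a3 (0.67) and the border-associated macrophage gene Stab1, which is also in the phagocytosis list, rose. The endothelial gene Bsg (-0.36) and the B cell gene Ighm (-0.38) fell. The oligodendrocyte gene Cnp (-0.22) and the neutrophil gene Csf3r (0.02) did not pass. No other cell type had 3 measured markers, so these values cannot tell whether other cells changed. With the within-library trend with GC content and exonic length removed, limma called 207 genes, 156 of them among the 428; 38 of the 62 called genes picked by the naming rule kept their call, and those that did not include Fcer1g (-0.02), Stab1 (0.365), Cd68 (-0.12) and Ctss (-0.12). After this removal the lysosomal list stayed low (median -0.32, camera adjusted p 1.84e-06), the immediate early list newly passed upward (0.30, 0.00695), and the other 6 lists, among them the plaque-associated (-0.10, 0.148), homeostatic (-0.07, 0.347), TGF-beta (0.34, 0.0651) and ribosomal (0.02) lists, no longer passed. The count was 69 without replicate 2 of APPPS1 given PBS, 222 without replicate 1 of that group, 222 without replicate 2 of APPPS1 given B. fragilis and 245 without replicate 4 of it, and 24 of the 62 called genes picked by the rule kept their call in each fit that left out 1 library, among them Ctsl, Ctsb, Ctsa, Cd9, Lars2, Zbtb7a and Srrm2.

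**Figure D2:**
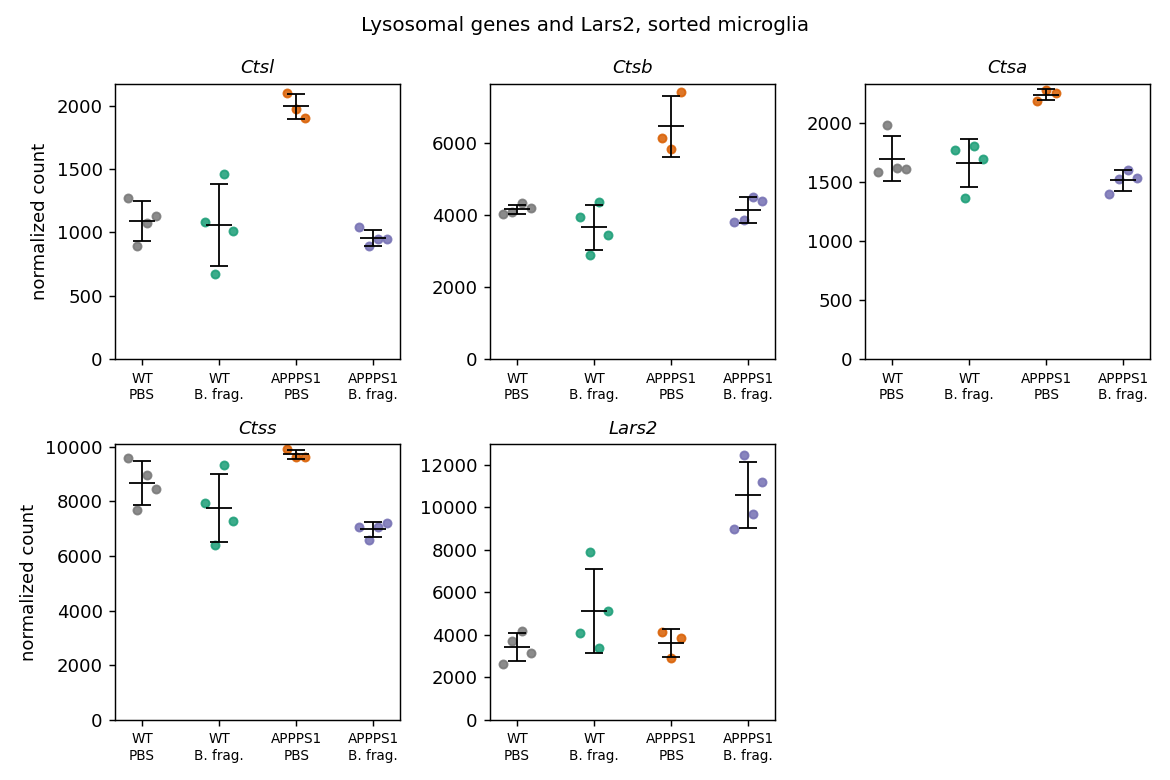
Normalized counts of 4 lysosomal genes and Lars2 in each of the 15 libraries, by genotype and treatment; points are libraries, horizontal bars are means and whiskers are 1 SD. In APPPS1, Ctsl had 1994 ± 100 with PBS and 957 ± 63.0 with B. fragilis, while Lars2 had 3613 ± 642 and 10570 ± 1550.

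Whether the treatment effect differed between genotypes was tested directly. Limma called 0 of 2757 genes (418 at an unadjusted p under 0.05, smallest adjusted p 0.101), so no single gene is shown to respond in one genotype and not in the other. Among the genes with the smallest p were Tmem30a (1.34), Tra2b (0.83), C1qc (1.39), Tmem259 (1.63) and Asap1 (1.23) toward a higher effect in APPPS1, and Cope (-0.97), the cystatin C gene Cst3 (-0.40), Cln8 (-1.49) and Ldhb (-0.61) toward a lower one. As groups, 6 lists differed by camera with the preset correlation. The effect in APPPS1 was lower for lysosomal (median difference -0.25, camera adjusted p 3.08e-05), plaque-associated (-0.35, 0.000616), proteasome (-0.33, 0.00254), oxidative phosphorylation (-0.23, 0.00738) and ribosomal protein genes (-0.25, 5.45e-09), and higher for TGF-beta signalling genes (0.48, 0.000822). None of these lists passed with an estimated correlation, with camera adjusted p = 0.285, 0.324, 0.324, 0.344, 0.344 and 0.244 in the same order. Fry, which does not set a list against other genes, passed the lysosomal (adjusted p 0.0234), proteasome (0.0313) and TGF-beta lists (0.0234). It did not pass the plaque-associated (fry adjusted p 0.0658), oxidative phosphorylation (0.0564) and ribosomal lists (0.0658). The plaque-associated and lysosomal lists share members. Limma called 33 genes without replicate 1 of APPPS1 given PBS, 28 without replicate 2 of wild type given B. fragilis and 1 without replicate 3 of that group, and with the GC content and exonic length trend removed only the lysosomal and TGF-beta lists passed camera. The oxidative phosphorylation list had a camera adjusted p of 0.0757 without replicate 3 of APPPS1 given PBS.

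Across genes, the B. fragilis effects in the 2 genotypes, which share no library, had a Pearson's r of 0.363 and a Spearman's rho of 0.363. Relabelled residuals gave r from -0.404 to 0.409, so the correlation alone lies within what the spread between libraries gives, while the covariance of 0.0452 lay above its relabelled range of -0.024 to 0.0245. Relabelled residuals hold no effects, so a large effect in APPPS1 alone can move the covariance out of that range. The covariance therefore does not show a shared effect. Of the 428 genes called in APPPS1, 318 (74.3%) had the same sign in wild type, and no relabelled range was computed for this share. Without replicate 2 of wild type given B. fragilis, r was 0.149.

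**Figure D3:**
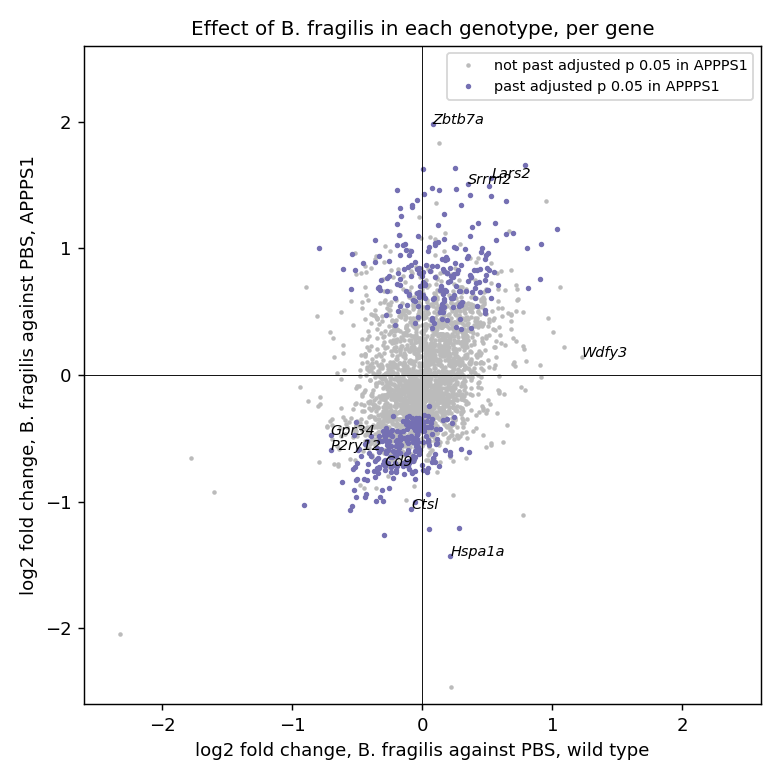
Log2 fold change of B. fragilis against PBS in wild type (x axis) and in APPPS1 (y axis) for the 2757 genes, of which 1 lies outside the axes; purple points are the 428 genes that limma called in APPPS1. Among the genes marked by name, Zbtb7a, Lars2 and Srrm2 rose in APPPS1, Ctsl and Hspa1a fell, and Wdfy3 lies to the right without passing.

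Averaged over both genotypes, Lars2 was higher with B. fragilis by 1.04 on the log2 scale, Zfp280d by 0.97, Fkbp5 by 0.90, Rhob by 0.72 and Zfp36l1 by 0.48. Cmtm6 (-0.72), Mob1a (-0.64), the selenium carrier gene Selenop (-0.53) and Cd9 (-0.50) fell, and limma adjusted p ran from 0.00162 to 0.00182 for these 9 genes, each of which kept its call in every fit that left out 1 library. Limma called 400 genes, 180 higher and 220 lower. Lysosomal genes fell in 15 of 39 cases and rose in 1 (median -0.24, camera adjusted p 3.89e-06), homeostatic genes fell in 7 of 20 and rose in 2 (-0.12, 0.00799), and ribosomal protein genes fell in 6 of 76 and rose in 1 (-0.11, 0.00126). Plaque-associated genes fell in 4 of 18 cases (-0.15, camera adjusted p 0.0148) and proteasome genes in 3 of 30 (-0.16, 0.0284), while immediate early genes rose in 8 of 25 (0.20, 0.00158). With an estimated correlation, camera adjusted p = 0.347 for the lysosomal list and 0.485 for the other 5. Of the 4 plaque-associated genes that fell, Ctsd, Ctsb and Ctsl are also in the lysosomal list. With the GC content and exonic length trend removed, the count was 187, and the homeostatic (camera adjusted p 0.0534), plaque-associated (0.304), proteasome (0.687) and ribosomal lists (0.273, median 0.02) no longer passed, as was so for the homeostatic (0.384) and plaque-associated (0.399) lists under quantile normalization. The count was 145 without replicate 2 of APPPS1 given PBS. The falls of 3 of these lists came mainly from APPPS1. In wild type alone the medians were -0.03 for plaque-associated, 0.02 for proteasome and 0.03 for ribosomal protein genes. None of them passed there (camera adjusted p 0.838, 0.905 and 0.504). In APPPS1 alone the medians were -0.29, -0.24 and -0.24.

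Among mice given B. fragilis, APPPS1 microglia again had higher plaque-associated genes than wild type. Cst7 rose from 20.1 ± 8.23 (SD, n = 4) to 778 ± 282 (SD, n = 4), a log2 fold change of 5.23 with a limma adjusted p of 4.31e-08, and Apoe from 754 ± 302 to 4411 ± 1130 (2.59). Ifi27l2a (2.50), Ank (2.31), Sdc3 (1.66), Lgals3bp (1.53), Cd52 (1.16), the chemokine gene Ccl6 (1.13), Lars2 (1.11) and Ramp1 (1.03) rose too. Hspa1a fell from 4258 ± 1820 to 1218 ± 157 (-1.71), and smaller falls were those of Atp2c1 (-0.84), Sgce (-0.76), Gmpr2 (-0.75), Akap8 (-0.75), Cmtm6 (-0.74), Upk1b (-0.68), the iron exporter gene Slc40a1 (-0.68), Sesn1 (-0.64) and Ecscr (-0.63). Lpl passed (1.01, limma adjusted p 0.047), while Trem2 (0.12), Tyrobp (0.36), Cd68 (0.17), P2ry12 (-0.40), Tmem119 (-0.22) and Cx3cr1 (-0.21) did not. Limma called 64 genes, 33 higher and 31 lower; with values rescaled to 1 upper quartile per library it called 66, 26 higher and 40 lower, so the balance of directions depends on the scaling. Array quality weights gave 205 genes, 98 higher and 107 lower, and a fit of the compared groups alone gave 21, 17 higher and 4 lower.

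By list, 7 of 18 plaque-associated genes rose (median 0.42, camera adjusted p 1.76e-14, and adjusted p = 0.0186 with an estimated correlation), and so did 2 of 9 lipid-handling genes, Apoe and Lpl (0.32, 0.000329, and adjusted p = 0.0186 with an estimated correlation). Apoe and Lpl are also in the plaque-associated list, so the rises of these lists are not separate results. Interferon response genes rose in 4 of 8 cases, with Bst2 (0.92) and Trim30a (0.84) beside Ifi27l2a and Lgals3bp (median 0.70, camera adjusted p 8.91e-07, and adjusted p = 0.066 with an estimated correlation). Ribosomal protein genes rose in 5 of 76 cases, for example Rpl41 (0.61), Rpsa (0.56), Rps28 (0.42) and Rpl36 (0.53), with a camera adjusted p of 2.27e-16 and an adjusted p = 0.132 with an estimated correlation. Homeostatic genes fell in 2 of 20 cases, among them P2ry13 (-0.45; camera adjusted p 0.000107, and adjusted p = 0.128 with an estimated correlation). The lists of glycolysis (Pkm 0.62), inflammatory (Cxcl16 0.73), TGF-beta (Bhlhe41 0.64) and antigen presentation genes were higher and those of immediate early (Jun -0.51) and proteasome genes lower, with camera adjusted p from 0.000326 to 0.0264 and adjusted p = 0.132 to 0.322 with an estimated correlation. Camera adjusted p passed 0.05 for proteasome genes without replicate 3 of wild type (0.145) or 4 of APPPS1 (0.0841), for immediate early genes without replicate 4 of wild type (0.0718) and for antigen presentation genes without replicate 3 of APPPS1 (0.0893), each given B. fragilis. Lysosomal genes did not pass as a list (camera adjusted p 0.361), with rises of Cd63 (0.61), Ctsz (0.42) and Grn (0.34). The count was 157 without replicate 2 of wild type given B. fragilis and 18 to 29 without any single one of 6 other libraries, namely replicates 1, 3 and 4 of wild type and 2, 3 and 4 of APPPS1 given B. fragilis. Of the 38 called genes picked by the naming rule, 13 kept their call in each fit that left out 1 library, among them Cst7, Apoe, Ank, Lgals3bp and Hspa1a.

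The genotype comparisons under PBS and under B. fragilis had 25 called genes in common, 23 higher in both and 2 lower in both, where independent calls would give 4.06. Across genes the 2 effects had a Pearson's r of 0.277, within the range of -0.429 to 0.406 from relabelled residuals, and a Spearman's rho of 0.0797, while the covariance of 0.0362 lay above its relabelled range of -0.0238 to 0.0231. The residuals hold no effects, so a large effect under PBS alone can move the covariance out of that range. Averaged over both treatments, APPPS1 microglia had higher Cst7 (5.59), Apoe (2.74), Lgals3bp (1.81), Cd52 (1.24) and Rpl41 (0.72) and lower P2ry13 (-0.51), Otulinl (-0.70), Cmtm6 (-0.55), Jun (-0.36) and Ivns1abp (-0.35). These 10 genes had limma adjusted p from 6.5e-11 to 0.00376 and kept their calls in every fit that left out 1 library. Limma called 228 genes, 158 higher and 70 lower, and the count was 136 without replicate 3 of APPPS1 given PBS. With an estimated correlation, 6 of the 11 lists that passed camera still passed, the plaque-associated, ribosomal, lipid-handling, interferon and glycolysis lists upward and the homeostatic list downward (adjusted p = 0.00248 to 0.0469).

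Genes that the APPPS1 genotype moved one way under PBS tended to move the other way with B. fragilis in APPPS1. Of 57 genes called in both comparisons, 35 were higher in APPPS1 and fell with B. fragilis, among them Ctsl, Ctsb, Ctsd, Hexa and Cd68, 20 were lower in APPPS1 and rose, among them C1qc, Ier2 and Zbtb7a, and 2 fell in both. Both comparisons use the 3 APPPS1 libraries given PBS with opposite sign, which alone gives a negative relation. Pearson's r across genes was -0.40, and relabelled residuals with the same shared libraries gave a mean of -0.568 and a range of -0.80 to -0.208. The covariance of -0.0667 also lay within its relabelled range of -0.0751 to -0.0103, so these data do not show an opposite movement beyond the shared libraries.

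**Figure D4:**
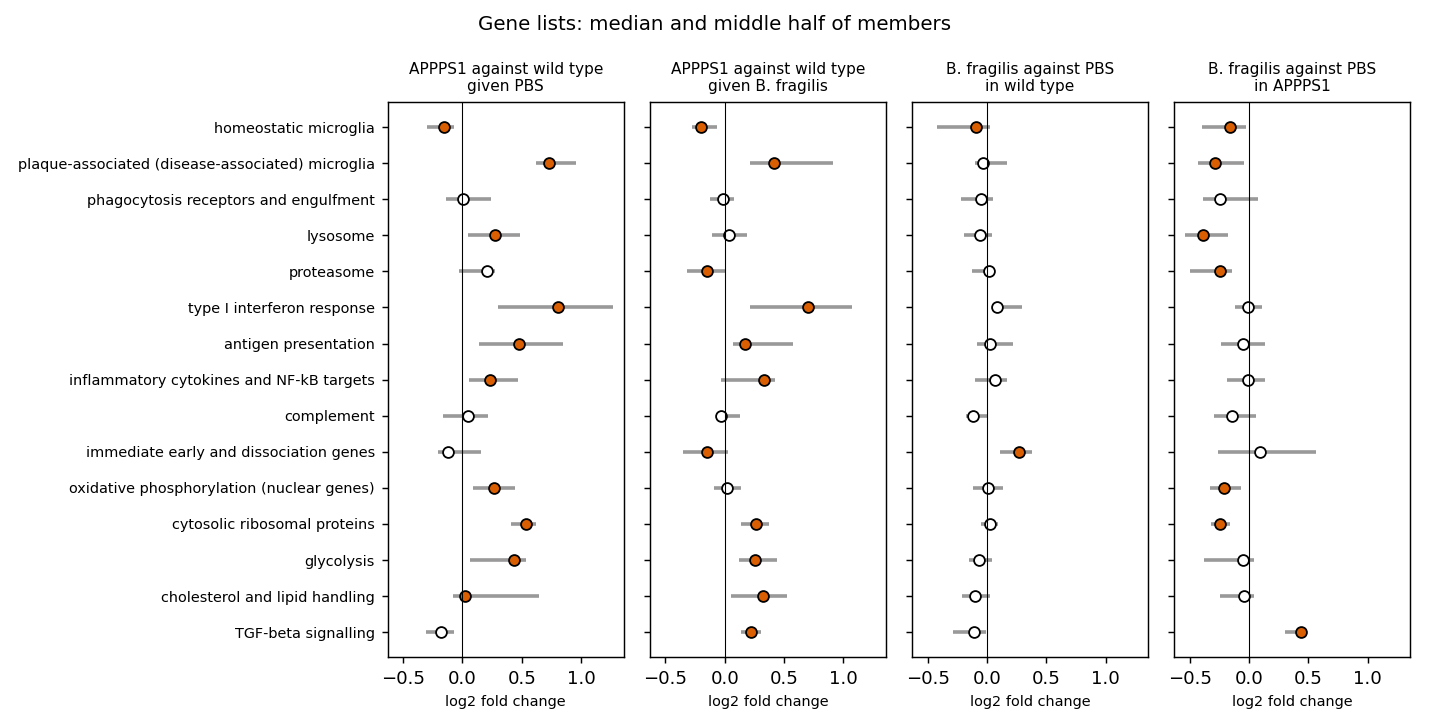
Median log2 fold change of each of 15 gene lists in the 4 pairwise comparisons; lines span the middle 50% of members, and filled points passed camera at adjusted p 0.05 with the preset correlation. The plaque-associated list lies at 0.73 and 0.42 in the genotype comparisons and the lysosomal list at -0.39 with B. fragilis in APPPS1.

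Against the authors' deposited tables, limma and the authors shared 376 calls for B. fragilis in APPPS1 (749 called by the authors), 158 for APPPS1 against wild type given PBS (254) and 53 for the same comparison given B. fragilis (92), each in the same direction. The authors' counts include genes that limma did not test. Among genes in both sources the authors called 644, 211 and 88 in the same order, and limma called 420, 175 and 60. Log2 fold changes correlated across genes with r of 0.941 to 0.99, and the authors' values were smaller, with slopes of 0.643 to 0.848.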

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

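The tests that remove GC content and exonic length trends, and the choice of regulator families, were made only after results had been seen. Other groupings of the same libraries were compared with the real ones. For B. fragilis in APPPS1, 1 of 35 splits, the real one, gave as many genes (428, highest other 4), so a chance split is an unlikely source of the count. The same holds for APPPS1 against wild type given PBS (1 of 35 splits, 175 against at most 3), for the same comparison given B. fragilis (1 of 35, 64 against 9), and for the mean effects of B. fragilis (1 of 100 splits, 400 against 2) and genotype (1 of 100, 228 against 9). The lowest share that 35 splits can give is 1 of 35. The other splits mix libraries of both groups, and plate position follows the real groups, so neither chance nor plate position is excluded. Where limma called 0 genes, every split reaches that count by construction, so the splits say nothing about chance. This holds for B. fragilis in wild type (35 of 35 splits, highest other 1) and for the difference between genotypes (100 of 100 splits, highest other 411). For the difference, the other splits that leave the APPPS1 treatment labels in place gave 0 to 411 genes (4 splits) and those that change them 0 to 2 (95 splits). Splits that leave the APPPS1 labels in place still hold the B. fragilis effect in APPPS1 (428 genes on its own). Their large counts are therefore no measure of chance.

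The lower lysosomal genes with B. fragilis in APPPS1 were weighed against technical explanations, for the lysosomal list and not for all 428 genes; the list passed camera with the preset correlation and not with an estimated one (adjusted p = 0.25). A trend with GC content and exonic length is argued against as the whole cause, because the list median stayed at -0.317 after its removal (-0.35 to -0.267 with 1 library left out, -0.39 without removal), although 9 of the 18 calls in the list remained and 3 others were added. Against reads from outside genes, added in proportion to length, 10000 lists matched on expression, length and GC content were drawn. The list median lay at percentile 0 of them (their central 95% ran from -0.27 to 0.00259). Matched genes were drawn singly, without the correlation between members of the list (estimated at 0.114). Their range may thus be too narrow, so the percentile does not decide on such reads. No single library carries the lower lysosomal median, since the value nearest to 0 with 1 library left out was -0.335. Cells of another type cannot be told apart from a change in the microglia, because 0 of 12 other cell types had 3 measured markers; plate position, which runs with treatment, also stays open beside an effect of B. fragilis, so the data are consistent with either.

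The higher ribosomal protein genes in APPPS1 given PBS were weighed in the same way. After removal of the trend with GC content and exonic length the list median was 0.365 (0.312 to 0.391 with 1 library left out, 0.54 without removal), with 29 of the 54 calls remaining. Without removal it lay at percentile 100 of 10000 matched lists (their central 95% ran from 0.00214 to 0.135), and the value nearest to 0 with 1 library left out was 0.477. These matched genes too were drawn singly, without the correlation between members (estimated at 0.338), so the range may be too narrow. Reads shared with ribosomal pseudogenes and other paralogs were not tested between groups and stay open, and 96.9% of the 25-base sequences of Rpl36 are shared. Plate position, which also runs with genotype, stays open too, so a higher share of ribosomal protein transcripts in APPPS1 microglia is a hypothesis.

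Splicing and chromatin genes were high among the genes that rose with B. fragilis in APPPS1, and 2 families named by symbol were tested without the members seen beforehand. The 78 remaining genes ranked above other genes (median 0.38, camera p 5.04e-07, and p = 0.00687 with an estimated correlation), with 17 of the 78 called higher, such as Kmt2d and Rbm25, and 1, Srsf6, lower. The 78 still include Rbm4b, named above among the large rises, so the test is not wholly independent of the leading genes. After removal of the GC content and exonic length trend the median was 0.187 (0.0756 to 0.214 with 1 library left out) and 2 were called higher, so a length trend cannot be told apart from a change of the families. These genes are long, with a median exonic length of 10580 bases against 4743 for all genes.

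Some lists differed between genotypes in their response to B. fragilis by camera with the preset correlation. The median differences, APPPS1 minus wild type, were -0.346 for plaque-associated, -0.248 for lysosomal, -0.332 for proteasome, -0.225 for oxidative phosphorylation, -0.247 for ribosomal protein and 0.478 for TGF-beta signalling genes. None of the 6 passed with an estimated correlation (camera adjusted p = 0.244 to 0.344), and of the 6 the lysosomal and TGF-beta lists passed after removal of the GC content and exonic length trend. By fry, the lysosomal, proteasome and TGF-beta lists passed and the others did not. Outside the table of values per library, the predicted gene Gm10800 had a log2 fold change of 0.96 with B. fragilis in APPPS1 in the authors' deposited table (adjusted p 0.00176). It and 7 like genes hold 62.4% of the summed means of that comparison in the authors' deposited table. What these sequences are, why they rose, and whether they affected the scaling of other genes was not tested.

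For the genes named in the text, single libraries far from the rest of their group were sought on the log2 scale in the 3 groups of 4. Of 474 pairs of gene and group, 32 (6.75%) had one, where chance gives about 1 in 20. Values are given against the range of the other libraries. In wild type given PBS, replicate 2 lay apart for Ctsa (1982 against 1584 to 1617), Hexa (1898 against 1639 to 1660), Lyz2 (523 against 479.9 to 484) and Tra2b (324 against 351 to 355). In wild type given PBS, replicate 1 lay apart for Nsd1 (182 against 214 to 220.5) and Tyrobp (2667 against 2531 to 2549). In wild type given PBS, replicate 4 was distant for Rplp0 (1103 against 1207 to 1215), Rpsa (564 against 650.2 to 665) and Uqcrh (108 against 158 to 164). In wild type given B. fragilis, replicate 2 stood out for C1qa (5129 against 5817 to 5892), Cd63 (434 against 522 to 540.4), Klf13 (48.4 against 121 to 139), Olfml3 (2665 against 3227 to 3324), P2ry13 (789 against 1003 to 1054), Psmc5 (189.5 against 148 to 154) and Sesn1 (212 against 265 to 274). In wild type given B. fragilis, replicate 3 was distant for Hexa (1827 against 1590 to 1621), Npc2 (919 against 808 to 812) and Tmem30a (133 against 106 to 109.9). In APPPS1 given B. fragilis, replicate 1 stood out for Apoe (2750 against 4806 to 5272), Ctsd (19360 against 24300 to 25340), Egr1 (9278 against 7792 to 8001), Sesn1 (199 against 147 to 154) and Sgce (119 against 88.9 to 91.8). In APPPS1 given B. fragilis, replicate 2 stood out for Atp2c1 (79.8 against 109 to 114), Cmtm6 (368 against 445 to 456) and Ythdc2 (242 against 139 to 151). In APPPS1 given B. fragilis, replicate 3 was distant for Fcer1g (2127 against 1844 to 1876), Mark2 (145 against 124 to 126) and Socs3 (466 against 544 to 562). In APPPS1 given B. fragilis, replicate 4 lay apart for Lgals3bp (681 against 849.6 to 879) and Stab1 (1112 against 1497 to 1538).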

How the results depend on the processing

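The removal of GC content and exonic length trends, and the list fit without replicate 2 of wild type given B. fragilis, were chosen after seeing the data. Outside the summary counts, 5524 values for genes picked by the naming rule and 2050 for lists kept their side of the threshold, 85 and 25 newly passed, 510 and 49 no longer passed, and 4 and 6 that passed in 1 of the fits changed direction. Among those that kept their side, 44 values for genes and 107 for lists changed sign without passing in either fit (151 over 50 results of at most 0.43 in size), and the others kept their direction. No filter and a mean of at least 50 removed 0 genes and so test nothing, and count models and a sex term were not run. Pseudocounts, rescaling by upper quartile and quantile normalization left each count of genes within 1.5 times. Quantile normalization changed which lists passed camera: for B. fragilis in APPPS1 the plaque-associated (adjusted p 0.0767) and homeostatic (0.912) lists no longer passed and the immediate early list did (0.00395), for the mean B. fragilis effect the plaque-associated (0.399) and homeostatic (0.384) lists no longer passed, and for APPPS1 against wild type given PBS the proteasome (0.0213), immediate early (0.00329) and TGF-beta (0.0327) lists newly passed. Read depth, and with it counting error, is unknown. Except where fewer libraries or genes entered the fit, the cause was not tested.

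With the GC content and exonic length trend removed, B. fragilis in APPPS1 gave 207 genes, its mean effect 187, and APPPS1 against wild type given PBS 117. Of the 175 genes called in the last without removal, 105 kept their call and 4 changed sign. The lists past the threshold were 4 (2 without removal) for B. fragilis in wild type, 2 (7) in APPPS1, of which the immediate early list is newly past it, 2 (6) for the difference between genotypes and 2 (6) for the mean effect. For the genotype they were 8 (10) under PBS, without the oxidative phosphorylation and inflammatory lists, 10 (11) under B. fragilis, without the proteasome list, and 10 (11) for the mean effect, without the oxidative phosphorylation list. With expression level removed as well, the genes were 186, 185 and, for APPPS1 against wild type given PBS, 111 (175), and the lists 4, 3, 2 and 3. In B. fragilis against PBS in APPPS1, camera's direction turned upward for the oxidative phosphorylation list (median -0.00129 and, with expression, 0.00793) and the ribosomal list (0.0159 and 0.0245), as it did for the ribosomal list for the mean B. fragilis effect (0.0206 and 0.0302). Among genes picked by the naming rule, the log2 fold change changed sign for C1qb for APPPS1 against wild type given PBS (-0.0349 and -0.0613) and, with expression, C1qb (0.0587) and Fcer1g (0.0287) for B. fragilis in APPPS1. The removal can also take away real differences tied to gene length, since ribosomal protein genes are short.

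Array quality weights gave 205 genes for APPPS1 against wild type given B. fragilis (64) and 8 for the difference between genotypes (0), and the compared groups alone gave 21 for the former. Camera with an estimated correlation passed 0 (2) and 0 (7) for B. fragilis in wild type and APPPS1, 4 (10) and 2 (11) for the genotype under PBS and B. fragilis, 0 (6) for the difference, 0 (6) and 6 (11) for the mean B. fragilis and genotype effects; fry passed 0, 8, 10, 8, 3, 7 and 10 lists in the same order.

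With 1 library left out, the count of genes ran from 0 to 8 for B. fragilis in wild type (8 without its replicate 3), 69 to 339 in APPPS1 (69 without replicate 2 of APPPS1 given PBS), 68 to 165 for the genotype under PBS (68 without replicate 3 of APPPS1 given PBS), 18 to 157 under B. fragilis (18 without replicate 2 of APPPS1, 157 without replicate 2 of wild type), 0 to 33 for the difference (33 without replicate 1 of APPPS1 given PBS), 145 to 531 for the mean B. fragilis effect (145 without replicate 2 of APPPS1 given PBS, and also 237, 223, 220, 218 and 245 without replicates 1 of wild type given PBS, 2 and 4 of wild type given B. fragilis, 1 of APPPS1 given PBS and 2 of APPPS1 given B. fragilis) and 136 to 264 for the mean genotype effect. Lists past the threshold ran from 1 to 3, 6 to 7, 10 to 13, 10 to 11, 5 to 6 and 5 to 6 in the same order, and was 11 in every fit for the mean genotype effect. The correlation between the B. fragilis effects of the genotypes ran from 0.149 (without replicate 2 of wild type given B. fragilis) to 0.441, that between the genotype effects from 0.19 to 0.314, and that between the B. fragilis effect in APPPS1 and the genotype effect from -0.496 to -0.367.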

Other observations

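The Ttr test and the families of regulators were chosen only after their values had been seen. Beyond the largest changes, B. fragilis in APPPS1 was accompanied by higher values of several histone methyltransferase and corepressor genes. With the members seen beforehand left out, limma called 10 of 41 chromatin genes higher and 0 lower, among them Baz1b (1.11), Kdm6b (1.10), Kmt2a (0.92), Kmt2c (0.71), Kmt2d (0.45), Ncor1 (0.86), Nsd1 (0.78), Srcap (0.91) and Tet3 (0.73). These 41 genes had a median of 0.50 (camera p 4.57e-08, and p = 0.0235 with an estimated correlation), and 0.21 with 1 gene called higher after removal of the GC content and exonic length trend. The 37 remaining splicing genes, which still include Rbm4b, had a median of 0.22 (camera p 0.0176, and p = 0.075 with an estimated correlation), and 0.04 with 1 gene called higher after that removal. In wild type the 78 genes of both families had a median of 0.07 (camera p 0.0142, and p = 0.134 with an estimated correlation). The difference between genotypes had a median of 0.18 (camera p 0.000183, and p = 0.0313 with an estimated correlation), and -0.01 after removal of the GC content and exonic length trend.

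Ttr, the transthyretin gene, varied between libraries of the same group. Its values were 0.79, 4.9, 54.6 and 0 in wild type given PBS, 10.7, 18.8, 2.6 and 0 in wild type given B. fragilis, 0, 382 and 106 in APPPS1 given PBS, and 1020, 202, 0 and 1099 in APPPS1 given B. fragilis. Choroid plexus, which expresses Ttr strongly, is a possible source, but 0 of the 5 other choroid plexus markers listed were measured, so this could not be tested.

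Replicate 2 of wild type given B. fragilis lay farthest from its group, with a root mean square deviation of 0.40 on the log2 scale and an array weight of 0.45. Across genes, fold changes correlated with exonic length with Spearman's rho of 0.0838 for B. fragilis in wild type, 0.447 in APPPS1, -0.321 for the genotype under PBS and 0.206 under B. fragilis.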
